A study of Mus musculus with 4 samples.

How the data were processed

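Polyadenylated RNA of mouse embryos from a cross of B6D2F1 males with ICR females was measured in the embryonic side (inner cell mass, ICM) and the extra-embryonic side (trophectoderm, TE) at the times labelled E4 and D10. Per the labels' protocols, each dissected tissue was lysed, reverse transcribed with a barcoded oligo-dT primer, and mixed with the other replicates of its group before PCR. This is the BRB-seq method, which reads the 3′ ends of transcripts. Read 1 held a molecular identifier (UMI) of 10 bases and a barcode of 9 bases, and read 2 an insert of 81 bases. The protocol text speaks of diapause embryos for the E4 samples too, while the series title speaks of before and after diapause, and the deposited barcode list marks E4 as before and D10 as day 6. These sources conflict. As replicates were mixed before PCR, each of the 4 groups was 1 amplification pool of 5 barcoded replicates, so that pool and group cannot be told apart. The values used were raw counts per gene and barcode, deposited by the authors as 1 table of 21470 genes and 20 libraries, of which 912 genes had 0 counts in every library. The submitters' processing notes name UMI-tools, Trim Galore 0.6.7, HISAT2 2.2.1 and featureCounts 2.0.1 and the builds GRCm38 and GRCh38, with no role or order. Whether the counts were collapsed by UMI, whether counting used strand, and which annotation was counted are not given in the sources used here.

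A deposited barcode list gives the litter and the presence of a zona pellucida for each library. The E4 replicates came from 5 litters, 2 with a zona and 3 without, and the D10 replicates from 5 other litters, all without. ICM and TE replicates with the same number came from the same litter within a time. Whether a library is 1 embryo or several is not stated, so p-values measure the spread between these libraries. Libraries of the same litter deviated together from their group means, with a mean correlation across genes of 0.177 at E4 (0.104 to 0.263 over 5 pairs) and 0.169 at D10 (-0.0302 to 0.293), against -0.0435 and -0.0418 for libraries of different litters. Deviations sum to 0 within a group, so the means for different litters follow largely from the others and give no separate baseline. Single pairs of different litters reached 0.0692 at E4 and 0.0893 at D10. Litter was therefore used as a block in an alternative for the comparisons of tissues and for the difference of the changes. Between E4 and D10 the litters differ, so a shared number pairs nothing.

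Total counts per library ran from 144276 to 1010354, and the number of genes with a count from 9458 to 14402. A count of 0 in a library allows up to 3 counts, which is 20.8 CPM (counts scaled to the size of the library) in the shallowest library and 2.97 CPM in the deepest. Because collapsing by UMI is not stated, counting intervals and such limits cover counting error only. No library had a total under 0.1 of the median, so 0 were left out, and 0 columns of per-sample values were left unused. No 2 libraries of a group matched within counting noise, with a lowest chi-square per degree of freedom of 2.57.

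The test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, on the 6943 genes that passed filterByExpr with a minimum count of 10, in 1 fit of all 4 groups. The 5 comparisons were D10 against E4 in the ICM, D10 against E4 in the TE, ICM against TE at E4, ICM against TE at D10, and the difference of the D10 minus E4 change between ICM and TE (the interaction). P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Values are log2 fold changes ± standard error (SE) of this fit, or mean CPM ± SD over 5 libraries with TMM factors. For a gene with 1 to 3 counts in a whole group, the ratio of the groups' pooled counts is given with an exact (Clopper-Pearson) 95% interval. For a group at 0, a lower bound is given against 3 counts over the group. In data simulated from these libraries for D10 against E4 in the ICM, over 6943 genes, the test recovered 39% of genes changed 2-fold and 96% of those changed 4-fold, and 6.25% of 144 calls were false. The simulation changed few genes, took the spread from its trend over expression level, and held no litter effect, pool effect or outlying library. These rates therefore describe the test under its own model and not its errors in the real data.

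Gene lists, 39 of them fixed before the data were examined, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. The 37 lists with at least 3 tested members gave 185 tests, adjusted together. The rule for naming genes was fixed at the same time. It took 10 lineage genes, and the 6 genes per direction with the smallest adjusted p among genes at or above the median level, leaving out clone names and pseudogenes (5 per direction for the interaction). It also took up to 3 members with the smallest adjusted p of each list that passed or had at least 3 members past the gene test. Of the last kind, a selection is given as examples of the lists described, and of the second kind most genes with shared 3′ sequence are left out. Lrp2's change in the ICM and genes said to have been chosen after their values were seen fall outside the rule.

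An 81-base read of a 3′ end cannot separate near-identical transcripts. A gene was counted as shared where at least 0.2 of the 31-base words in the last 600 bases of its transcripts occurred in a transcript of another gene of the GENCODE M21 annotation of GRCm38, which was the case for 3028 of the genes in the table. Overlaps of the last 300 bases of a 3′ exon with another gene were listed as well. Both kinds are marked as uncertain in the text where such a gene is named. Counts of list members include such genes, in most cases without a mark. Coordinates come from the same annotation. Alternatives fixed beforehand were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma voom with quality weights, no filter, a minimum count of 30, fits of only the groups compared, libraries thinned to 144276 counts, a replicate block, and leaving out each replicate in turn. Chosen after seeing the data were leaving out the E4 replicates with a zona, leaving out shared genes and pseudogenes, and the litter block for gene lists. Alternative splits of the samples were drawn 100 at a time.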

Results

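Gene expression was measured separately in the embryonic side (inner cell mass, ICM) and the extra-embryonic side (trophectoderm, TE) of mouse embryos at the times labelled E4 and D10. The series title speaks of before and after embryonic diapause, while the protocols call the dissected embryos of both times diapause embryos. Diapause is a reversible arrest of the blastocyst before implantation. The data comprised 20 libraries in 4 groups of 5, each sequenced from the 3′ ends of polyadenylated transcripts. Total counts per library were 315990 ± 116730 (SD, n = 5) in E4 ICM, 307620 ± 167560 in E4 TE, 467300 ± 358100 in D10 ICM and 536660 ± 55329 in D10 TE. The first principal component of the log2 CPM values (CPM, counts scaled to the size of the library) held 31.8% of the variance and separated ICM from TE. The second held 22.5% and separated E4 from D10.

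**Figure D1:**
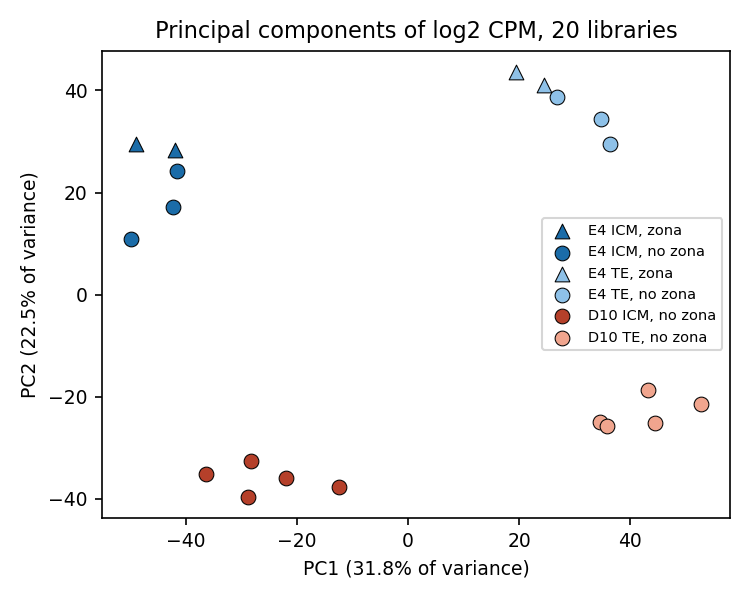
Principal component scores of the 20 libraries, with PC1 (31.8% of the variance) on the horizontal and PC2 (22.5%) on the vertical axis. Each point is 1 library, coloured by group, triangles mark E4 libraries from litters with a zona, and the 4 groups do not overlap.

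Lists of genes fixed before the data were examined were tested as sets, and 71 of 185 tests of a list in a comparison passed at a preset correlation between genes. With a correlation estimated from the data 10 passed, and all 10 were among the 71. They comprised the epiblast list in the ICM across time (0.0346) and between the tissues at E4 (0.000668) and D10 (0.000263), with the adjusted p in parentheses. The trophectoderm list passed between the tissues at E4 (0.00584) and D10 (0.0346), and the primitive endoderm list at D10 (0.0163). The others were the quiescence list across time in the ICM (0.00584) and the TE (0.0393), the oocyte list across time in the TE (0.0346) and the cholesterol list for the difference of the changes (0.0463). The other 61 set results rest on the preset correlation.

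The comparison of ICM with TE at E4 asked which genes distinguished the tissues at the earlier time. In the epiblast list, the markers of the pluripotent lineage, 16 of 23 tested genes were higher and 2 lower (16 and 2 adjusted over the list alone, set test adjusted p = 8.63e-19). Sox2 (ENSMUSG00000074637, GRCm38 chromosome 3, 34650405 to 34652461, plus strand), a transcription factor of pluripotent cells, had 421 counts in the ICM and 1 in the TE, a ratio of 366 (95% interval 65.3 to 14500). Tdgf1 (ENSMUSG00000032494, GRCm38 chromosome 9, 110939603 to 110946158, minus strand), a co-receptor for Nodal, had a ratio of 434 (95% interval 120 to 3590). Nanog (ENSMUSG00000012396, GRCm38 chromosome 6, 122707489 to 122714633, plus strand), another pluripotency factor, was higher in the ICM by 4.48 ± 0.55 on the log2 scale (adjusted p = 1.52e-06). The log2 difference was also positive for Utf1, 5.26 ± 0.41 (adjusted p = 2e-09), and for Upp1, uridine phosphorylase, 4.55 ± 0.41 (adjusted p = 2.27e-08). Pou5f1 (ENSMUSG00000024406, GRCm38 chromosome 17, 35506018 to 35510772, plus strand) had 8 counts over the E4 ICM libraries, 1 over the D10 ICM libraries and 0 in either TE group, and was not tested. Its 3′ end overlaps a gene annotated on the opposite strand, so its level is uncertain.

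Primitive endoderm markers were also on the ICM side at E4, where 18 of 24 tested genes were higher and 1 lower (19 and 2 adjusted over the list alone, set test adjusted p = 3.15e-08). Sox17 and Gata4, transcription factors of that lineage, were higher by 5.19 ± 0.65 and 4.59 ± 0.72, and Gata6 by 1.51 ± 0.32 (adjusted p = 1.86e-06, 3.17e-05 and 0.000732). Of the 5 Gata4 counts in the E4 TE, 4 were in replicate 5, so the size of its difference depends on that library. In the trophectoderm list, 1 of 29 tested genes were higher and 20 lower (1 and 23 adjusted over the list alone, set test adjusted p = 2.33e-12). As defined, this list shares Lrp2 and Dab2 with the primitive endoderm list, so the results of these lists are not independent in any comparison. Gata3 (ENSMUSG00000015619, GRCm38 chromosome 2, 9857078 to 9890034, minus strand), a trophectoderm transcription factor, stood at 408 ± 49.9 CPM in the ICM and 1570 ± 371 in the TE (log2 -1.96 ± 0.21, adjusted p = 2.86e-07). Eomes was lower in the ICM (log2 -1.78 ± 0.23, adjusted p = 2.64e-06), and Cldn4, a tight junction protein, likewise (log2 -2.15 ± 0.24, adjusted p = 4.93e-07). Krt8, at 213 ± 64.1 and 371 ± 121 CPM, did not pass (log2 -0.82 ± 0.34, adjusted p = 0.0684). Cdx2 (ENSMUSG00000029646, GRCm38 chromosome 5, 147300805 to 147307270, minus strand) passed narrowly (log2 -0.89 ± 0.33, adjusted p = 0.0415). It no longer passed with DESeq2's Wald test, with limma voom or without the low-count filter, or with E4 ICM replicate 3, 4 or 5 or E4 TE replicate 2 or 3 left out, where the adjusted p reached 0.149.

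**Figure D2:**
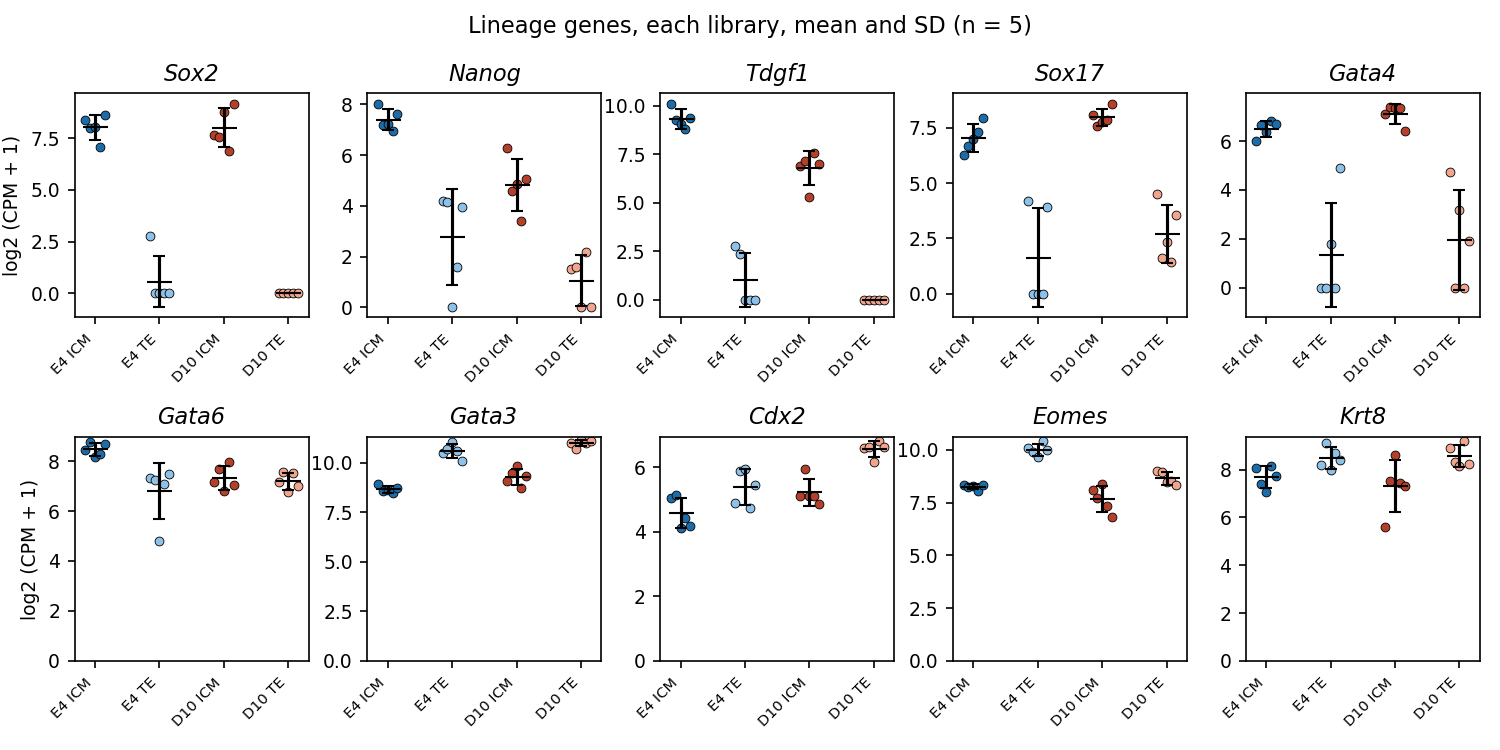
Expression of 10 genes as log2 (CPM + 1) on the vertical axis in the 4 groups on the horizontal axis, where each point is 1 library and the bars give the mean and SD (n = 5). Sox2 had 1 count in the 5 E4 TE libraries and 0 in the 5 D10 TE libraries, while Gata3, Eomes and Krt8 were counted in all 4 groups.

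Genes of the S phase, ribosome biogenesis and Myc target lists were higher on the ICM side at E4. In the S phase list 27 of 47 tested genes were higher and 0 lower (32 and 0 adjusted over the list alone, set test adjusted p = 4.65e-11), with Uhrf1, which maintains DNA methylation at replication, higher by 3.19 ± 0.38. Of ribosome biogenesis factors 29 of 46 tested genes were higher and 0 lower (32 and 0 adjusted over the list alone, set test adjusted p = 6.16e-09), among them Nolc1 by 1.57 ± 0.24. Of classic Myc targets 14 of 23 tested genes were higher and 0 lower (15 and 0 adjusted over the list alone, set test adjusted p = 8.06e-07), including Srm, spermidine synthase, by 1.99 ± 0.26. The mitosis list had 15 higher and 1 lower of 52 (adjusted p = 0.000494) and chromatin regulators 12 higher and 1 lower of 34 (adjusted p = 0.00127). Heat shock genes had 11 higher and 1 lower of 24 (adjusted p = 0.0213), translation factors 10 higher and 0 lower of 36 (adjusted p = 0.025) and the Wnt pathway 6 higher and 2 lower of 13 (adjusted p = 0.0355). In the other direction, actin cytoskeleton genes had 1 higher and 22 lower of 36 (adjusted p = 4.97e-08), with Msn, moesin, at log2 -3.18 ± 0.39. Respiratory chain genes had 0 higher and 19 lower of 76 (adjusted p = 0.000494), and genes of lipid use 2 higher and 11 lower of 34 (adjusted p = 0.012). Autophagy and lysosome genes had 6 higher and 16 lower of 48 (adjusted p = 0.017) and mural trophectoderm and giant cell markers 2 higher and 4 lower of 9 (adjusted p = 0.0494). The Wnt list did not pass without E4 ICM replicate 4 or E4 TE replicate 4 (adjusted p up to 0.0909), nor the heat shock list without E4 ICM replicate 1 or E4 TE replicate 2 or 5 (up to 0.0844). Translation factors did not pass without E4 ICM replicate 1 or E4 TE replicate 5 (up to 0.0691) and the mural list with any 1 of 14 libraries left out (up to 0.102). Glud1, glutamate dehydrogenase, was higher in the ICM (log2 1.85 ± 0.17, adjusted p = 3.44e-08), while Psap, the precursor of lysosomal saposins, and Mbnl3, a splicing regulator, were lower (log2 -2.11 ± 0.22 and -3.04 ± 0.31).

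Over all 6943 genes tested by edgeR's quasi-likelihood test, 1094 were higher and 1071 lower in the E4 ICM than in the E4 TE. The counts fell to 568 and 662 with all libraries thinned to 1 total, and a stricter count minimum gave 660 higher genes.

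The comparison of ICM with TE at D10 asked the same at the later time. In the primitive endoderm list 20 of 24 tested genes were higher and 0 lower (20 and 1 adjusted over the list alone, set test adjusted p = 1.38e-21). Sparc, a matrix protein, was higher in the ICM by 6.12 ± 0.55, Sox17 by 4.92 ± 0.49 and Gata4 by 4.18 ± 0.54 (adjusted p = 1.58e-08, 7.83e-08 and 2.29e-06), while Gata6 did not pass (log2 0.22 ± 0.30, adjusted p = 0.656). Of the 20 Sox17 and 19 Gata4 counts in the D10 TE, 12 and 14 were in replicate 1, so the sizes of these differences depend on that library. In the epiblast list 15 of 23 tested genes were higher and 1 lower (16 and 2 adjusted over the list alone, set test adjusted p = 4.74e-14). Sox2 had 470 counts in the ICM and 0 in the TE, at least 179-fold higher, and Tdgf1 was at least 124-fold higher. Nanog was higher by 3.91 ± 0.73 (adjusted p = 0.000215). In the trophectoderm list 2 of 29 tested genes were higher and 19 lower (3 and 21 adjusted over the list alone, set test adjusted p = 4.87e-07). Gata3 stood at 646 ± 181 CPM in the ICM and 2060 ± 231 in the TE (log2 -1.68 ± 0.21, adjusted p = 1.39e-06). Cdx2 stood at 37.8 ± 13.2 and 94.3 ± 14.6 (log2 -1.25 ± 0.27, adjusted p = 0.00109) and Eomes at 217 ± 88.6 and 406 ± 84.3 (log2 -0.93 ± 0.23, adjusted p = 0.00397). Krt8 was lower in the ICM (log2 -1.06 ± 0.34, adjusted p = 0.0212), but did not pass in thinned libraries or without D10 ICM replicate 1 or 5 or D10 TE replicate 4, where the adjusted p reached 0.103. Markers of polar trophectoderm and trophoblast stem cells had 8 higher and 4 lower of 15 (adjusted p = 0.0205). That list includes Sox2 and Esrrb of the epiblast list, and Bmp4, which was hardly counted in the D10 TE. Its members Cdx2 and Eomes were lower in the ICM, so the result does not show trophoblast identity in the ICM.

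Cholesterol synthesis genes separated the tissues at D10, where 17 of 20 tested genes were higher and 0 lower (18 and 0 adjusted over the list alone, set test adjusted p = 3.76e-13), with a median log2 difference of 2.62. At E4 the same list had 0 higher and 2 lower of 20 (adjusted p = 0.51) and a median of -0.18. Srebf2 (ENSMUSG00000022463, GRCm38 chromosome 15, 82147181 to 82205379, plus strand), a transcription factor that controls the pathway, was higher in the D10 ICM by 4.44 ± 0.44 (adjusted p = 6.77e-08), and Sqle, squalene epoxidase, by 3.27 ± 0.38. Elovl5, a fatty acid elongase, was higher by 3.82 ± 0.30 (adjusted p = 1.59e-09). Genes of lipid use as a list had 2 higher and 13 lower of 34 (adjusted p = 0.00553), with Cidea, a lipid droplet protein, at log2 -5.57 ± 0.63.

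Genes of the cell cycle were higher in the D10 ICM than in the D10 TE. In the mitosis list 29 of 52 tested genes were higher and 0 lower (36 and 0 adjusted over the list alone, set test adjusted p = 8.7e-10), with Plk1 (ENSMUSG00000030867, GRCm38 chromosome 7, 122159439 to 122169873, plus strand), a mitotic kinase, higher by 3.29 ± 0.51. In the S phase list 20 of 47 tested genes were higher and 0 lower (23 and 0 adjusted over the list alone, set test adjusted p = 6.92e-06). Myc targets had 11 higher and 0 lower of 23 (adjusted p = 0.00122), ribosome biogenesis factors 12 higher and 0 lower of 46 (adjusted p = 0.00378). Immediate early genes had 6 higher and 0 lower of 15 (adjusted p = 0.0102), the Wnt pathway 5 higher and 1 lower of 13 (adjusted p = 0.00553) and oocyte genes 3 higher and 0 lower of 3 (adjusted p = 0.00183). In the other direction, the actin cytoskeleton list had 2 higher and 11 lower of 36 (adjusted p = 0.00111), and 23 did not pass. Respiratory chain genes had 2 higher and 13 lower of 76 (adjusted p = 0.00337), and 61 did not pass. With the estimated correlation neither set test passed (adjusted p = 0.36 and 0.712). The autophagy and lysosome list had 6 higher and 12 lower of 48, and 30 did not pass (set test adjusted p = 0.0459, and 0.439 with the estimated correlation). This list did not pass with litter as a block (adjusted p = 0.0702) or without E4 ICM replicate 4, D10 ICM replicate 1, 2 or 5 or D10 TE replicate 3 (up to 0.134). The 3 oocyte genes did not pass with any 1 of 15 libraries left out (up to 0.187). Tdh, threonine dehydrogenase, was higher in the ICM by 6.25 ± 0.57 and Dkk1, a Wnt antagonist, by 6.30 ± 0.61. In the D10 TE both were counted in replicate 1 only (18.25 and 10.95 CPM), and without it their level there was 0. Gata4, Sox17 and Sparc were also highest in that library among those of the D10 TE (25.55, 21.9 and 180.69 CPM, against at most 8.02, 10.93 and 64.19). Lower were Psap (log2 -2.73 ± 0.23), Gstm5, a glutathione transferase (log2 -3.36 ± 0.30) and Gjb2, a gap junction protein (log2 -5.06 ± 0.46).

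At D10, 898 genes were higher and 873 lower in the ICM than in the TE. Thinned libraries gave 443 and 459, a stricter count minimum 596 and 574, and no filter 1474 higher genes.

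The comparison of D10 with E4 in the ICM asked what changed on the embryonic side over time. Inhibitors of cyclin-dependent kinases and other genes linked to quiescence rose: 7 of 12 tested genes were higher and 0 lower (7 and 0 adjusted over the list alone, set test adjusted p = 4.69e-07), with a median log2 change of 1.91. Cdkn1a, the inhibitor p21 (ENSMUSG00000023067, GRCm38 chromosome 17, 29090976 to 29100727, plus strand), went from 2.92 ± 4.06 to 224 ± 109 CPM (log2 6.16 ± 0.69, adjusted p = 9.95e-07). Ccng1 rose by 3.61 ± 0.47 and Pdcd4, an inhibitor of translation initiation, by 2.70 ± 0.29 (adjusted p = 7.64e-06 and 5.96e-07). Of p53 target and apoptosis genes 11 of 23 tested genes were higher and 1 lower (12 and 1 adjusted over the list alone, set test adjusted p = 2.24e-05), with Bcl2l1, which opposes apoptosis, higher by 2.23 ± 0.28. As defined, this list shares Cdkn1a, Ccng1, Btg2 and Trp53inp1 with the quiescence list, so the results of these lists are not independent. S100a1 (ENSMUSG00000044080, GRCm38 chromosome 3, 90511034 to 90514392, minus strand), a calcium-binding protein, had 2 counts over the E4 ICM libraries and 1505 over the D10 ICM libraries, a ratio of 587 (95% interval 162 to 4850). S100a1 rose strongly in the TE too, and the trophectoderm gene Gata3 was counted in every ICM library. How much of the S100a1 rise came from trophectoderm in the ICM libraries was not tested. Rhox5, an X-linked homeobox gene, rose by 5.06 ± 0.52 (adjusted p = 2.03e-07) and Tspan9 by 3.00 ± 0.29 (adjusted p = 1.15e-07).

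Epiblast genes fell in the ICM, where 1 of 23 tested genes were higher and 13 lower (2 and 14 adjusted over the list alone, set test adjusted p = 5.71e-07). Nanog went from 174 ± 54.6 to 33.8 ± 25.2 CPM (log2 -2.55 ± 0.43, adjusted p = 0.000158) and Tdgf1 from 666 ± 255 to 123 ± 54.5 CPM (log2 -2.35 ± 0.31, adjusted p = 2.36e-05). Sox2 stood at 277 ± 99.6 CPM at E4 and 303 ± 193 at D10, a difference within the spread between replicates (log2 0.10 ± 0.36, adjusted p = 0.871). Primitive endoderm genes moved the other way, and 11 of 24 tested genes were higher and 1 lower (11 and 1 adjusted over the list alone, set test adjusted p = 5.77e-05). Cubn, an endocytic receptor, rose by 3.22 ± 0.48. The lineage factors Sox17 (log2 0.84 ± 0.37, adjusted p = 0.102) and Gata4 (log2 0.62 ± 0.42, adjusted p = 0.302) did not pass. Gata6 was lower at D10 (log2 -1.04 ± 0.30, adjusted p = 0.0139), a call that was lost without the E4 litters that had a zona, the glycoprotein shell of the embryo (log2 -0.91, adjusted p = 0.0889).

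The trophectoderm list had 11 higher and 2 lower of 29 (adjusted p = 0.0155) in the ICM across time, and did not pass without D10 ICM replicate 3 (adjusted p = 0.0533). Its member Gata3 (log2 0.66 ± 0.21, adjusted p = 0.0229) did not pass without that replicate, without E4 ICM replicate 4 (adjusted p up to 0.0737), without the E4 litters with a zona or without the filter. Cdx2, Eomes and Krt8 did not pass either (log2 0.75 ± 0.32, -0.50 ± 0.24 and -0.16 ± 0.34, adjusted p = 0.0916, 0.125 and 0.781). The actin cytoskeleton list had 11 higher and 1 lower of 36 (adjusted p = 0.00553). The trophectoderm and actin lists were both lower in the ICM than in the TE at E4. More trophectoderm in the D10 ICM libraries could therefore raise them, which was not tested.

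Proteasome and heat shock genes fell in the ICM. Of proteasome subunits 0 of 33 tested genes were higher and 22 lower (0 and 25 adjusted over the list alone, set test adjusted p = 1.94e-12), with a median log2 change of -0.82. Psmd2 (log2 -1.44 ± 0.24) and Psmb3 (log2 -1.49 ± 0.25) were among them, but both share 3′ sequence with other genes and are uncertain. Of heat shock genes 1 of 24 tested genes were higher and 12 lower (2 and 13 adjusted over the list alone, set test adjusted p = 5.71e-07), with Hsph1 at log2 -1.87 ± 0.26. Ribosome biogenesis factors had 0 higher and 12 lower of 46 (adjusted p = 7.91e-05), with Ubtf and Polr1a of the RNA polymerase I machinery at log2 -1.80 ± 0.36 and -1.61 ± 0.33. Chromatin regulators had 3 higher and 14 lower of 34 (adjusted p = 0.00365), with Uhrf1 at log2 -1.68 ± 0.32 and Tet1, a DNA demethylase, at -1.72 ± 0.33. Also lower were Macroh2a1, a histone variant (log2 -1.76 ± 0.23, adjusted p = 8.03e-06), and Calcoco2, an autophagy receptor (log2 -4.13 ± 0.48, adjusted p = 1.83e-06). Fbp2, a gluconeogenic enzyme, was lower as well (log2 -2.77 ± 0.38). Mars1, methionyl-tRNA synthetase (log2 -1.91 ± 0.24, adjusted p = 6.5e-06), overlaps a gene on the opposite strand at its 3′ end and is uncertain.

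Cholesterol synthesis genes rose in the ICM, where 12 of 20 tested genes were higher and 0 lower (17 and 0 adjusted over the list alone, set test adjusted p = 8.64e-05), with a median log2 change of 1.25. D10 ICM replicate 3 went the other way, with a mean of the list, as log2 (CPM + 1), of 4.99 against 5.43 to 5.72 in the E4 ICM libraries. That library also had the highest share of mitochondrial counts of all 20 (18.9%). Among the D10 ICM libraries it lay nearest to the TE on the first principal component (-12.5 against -36.3 to -22) and was highest in Gata3 (903 CPM against 420 to 707), Krt8 (393 against 47.5 to 183), Eomes (332 against 111 to 276) and Msn (670 against 89.2 to 338), but lowest in Cldn4 (438 against 466 to 1150). Without it the list passed with an adjusted p of 4.75e-10. Glycolysis genes had 6 higher and 0 lower of 14 (adjusted p = 0.000793), with the glucose transporter Slc2a3 higher by 1.20 ± 0.22. Of the 14 genes, 7 share 3′ sequence with other genes and are uncertain. The median log2 change of the list was 0.898 with them and 0.799 without. Mitosis genes had 1 higher and 5 lower of 52 (adjusted p = 0.00392). The S phase list had 0 higher and 8 lower of 47 (adjusted p = 0.00567) and did not pass without D10 ICM replicate 3 (adjusted p = 0.0514). Translation factors had 2 higher and 8 lower of 36 (adjusted p = 0.0322) and did not pass without E4 ICM replicate 1 or D10 ICM replicate 4 or 5 (up to 0.112). Uterine markers, of which 5 were tested, had 2 higher and 0 lower of 5 (adjusted p = 0.0458) and did not pass without E4 ICM replicate 4 or D10 ICM replicate 2 (up to 0.0615). The 3 tested oocyte genes had 0 higher and 2 lower of 3 (adjusted p = 0.0186), a call that was lost with any 1 of 11 libraries left out (up to 0.0928).

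Across the ICM comparison 951 genes were higher and 692 lower at D10. Thinned libraries gave 509 and 360, and without the E4 libraries that had a zona 379 genes were lower.

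**Figure D3:**
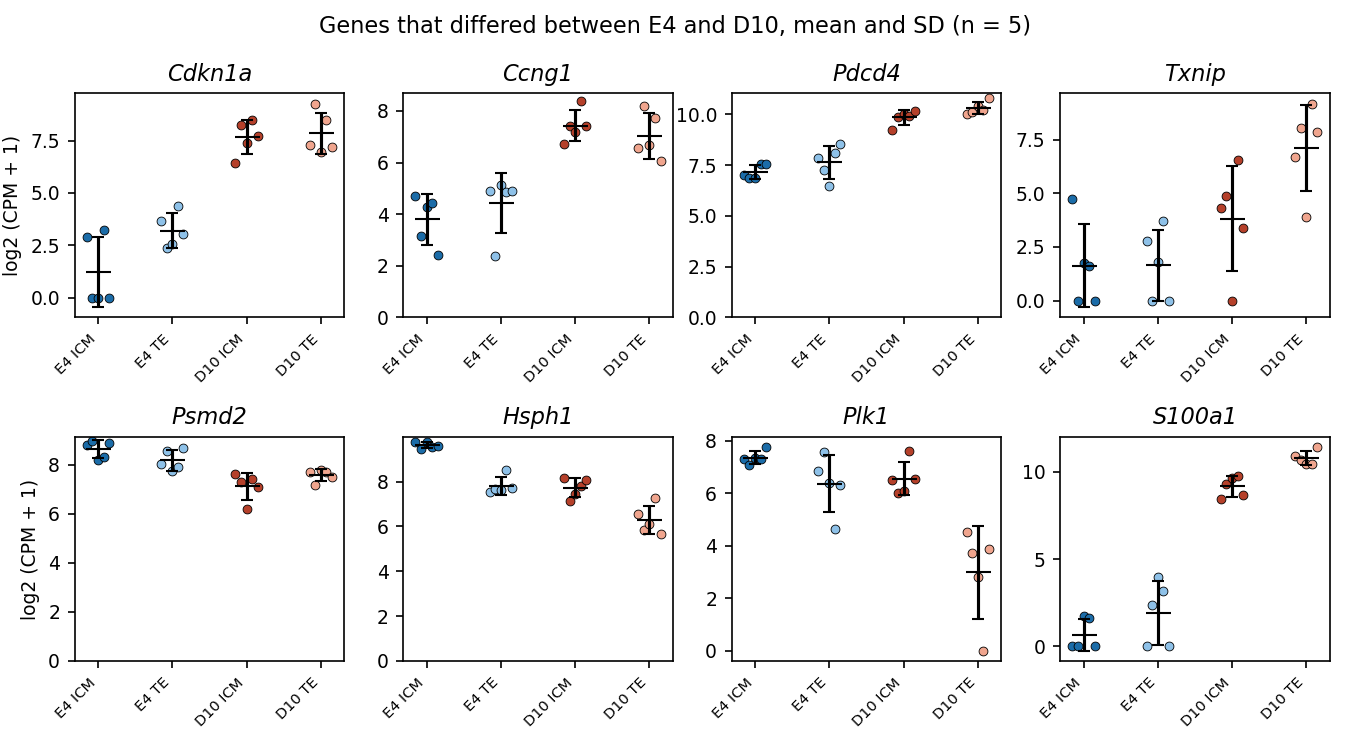
Expression of 8 genes as log2 (CPM + 1) on the vertical axis in the 4 groups on the horizontal axis, where each point is 1 library and the bars give the mean and SD (n = 5). Cdkn1a and S100a1 were higher at D10 than at E4 in both tissues, and Plk1 was lowest in the D10 TE, at 10.8 ± 8.26 CPM.

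The comparison of D10 with E4 in the TE asked the same for the extra-embryonic side. Mitosis genes fell: 0 of 52 tested genes were higher and 17 lower (0 and 20 adjusted over the list alone, set test adjusted p = 1.61e-07). Plk1 went from 98.2 ± 61.2 to 10.8 ± 8.26 CPM (log2 -3.12 ± 0.53, adjusted p = 0.000117), and Cenpa, the centromeric histone, fell by 1.63 ± 0.27 on the log2 scale. Of quiescence genes 5 of 12 tested genes were higher and 1 lower (6 and 1 adjusted over the list alone, set test adjusted p = 0.00174). Without the E4 litters with a zona that list did not pass (adjusted p = 0.0512). Cdkn1a went from 9.52 ± 6.49 to 279 ± 208 CPM (log2 4.68 ± 0.58, adjusted p = 2.09e-06), and Pdcd4 and Ccng1 rose by 2.57 ± 0.29 and 2.57 ± 0.45. Of p53 target and apoptosis genes 12 of 23 tested genes were higher and 1 lower (13 and 1 adjusted over the list alone, set test adjusted p = 2.08e-05), with Trp53 itself higher by 2.29 ± 0.39 and Zmat3 by 2.91 ± 0.50. The overlap of this list with the quiescence list applies here too. Txnip, an inhibitor of glucose uptake, rose by 5.40 ± 0.91 (adjusted p = 0.000117).

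Cholesterol synthesis genes fell in the TE, where 0 of 20 tested genes were higher and 13 lower (0 and 13 adjusted over the list alone, set test adjusted p = 3.62e-07), with a median log2 change of -1.26. Sqle (ENSMUSG00000022351, GRCm38 chromosome 15, 59315077 to 59331192, plus strand) went from 97.4 ± 42 to 13.7 ± 6.74 CPM (log2 -2.79 ± 0.40, adjusted p = 1.37e-05). Proteasome subunits had 0 higher and 11 lower of 33 (adjusted p = 1.77e-05) and heat shock genes 1 higher and 9 lower of 24 (adjusted p = 0.000234). Genes of the integrated stress response had 2 higher and 8 lower of 22 (adjusted p = 0.0122), and did not pass without E4 TE replicate 3, D10 TE replicate 2 or D10 ICM replicate 4 (adjusted p up to 0.302). Antioxidant genes had 2 higher and 4 lower of 29 (adjusted p = 0.0191), and did not pass without D10 TE replicate 3 (adjusted p = 0.0696).

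Among lineage genes of the TE, Eomes fell from 1050 ± 212 to 406 ± 84.3 CPM (log2 -1.36 ± 0.23, adjusted p = 9.56e-05) and Cdx2 rose from 43.3 ± 16.1 to 94.3 ± 14.6 CPM (log2 1.11 ± 0.28, adjusted p = 0.00491). Gata3 (log2 0.39 ± 0.20, adjusted p = 0.178), Krt8 (log2 0.08 ± 0.33, adjusted p = 0.895) and Gata6 (log2 0.25 ± 0.32, adjusted p = 0.615) did not pass. S100a1 went from 5.34 ± 6.15 to 1810 ± 553 CPM (log2 7.91 ± 0.43, adjusted p = 6.76e-13), and Gstm5 and S100a13 rose by 6.17 ± 0.43 and 5.79 ± 0.51. Gjb2 (ENSMUSG00000046352, GRCm38 chromosome 14, 57098600 to 57104702, minus strand) had 0 counts in the E4 TE and was at least 1160-fold higher at D10. Il1rn, the interleukin 1 receptor antagonist, had a ratio of 338 (95% interval 60.5 to 13400). Alppl2, an alkaline phosphatase (ENSMUSG00000026246, GRCm38 chromosome 1, 87086694 to 87089928, minus strand), fell from 349 ± 191 to 5.24 ± 3.55 CPM (log2 -5.94 ± 0.54, adjusted p = 1.72e-08), and Gsta4, a glutathione transferase, was lower (log2 -2.53 ± 0.22). The 3 tested oocyte genes had 0 higher and 2 lower of 3 (adjusted p = 7.91e-05), with Ooep at log2 -4.79 ± 0.45. Without the filter, or without genes that share 3′ sequence, that list did not pass (adjusted p = 0.198 and 0.168).

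In the TE 826 genes were higher and 687 lower at D10. Thinned libraries gave 410 and 354, and a stricter count minimum gave 531 higher genes.

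The changes of the ICM and the TE were then compared with each other. Across the 6943 genes, which are not independent replicates, the log2 changes of the tissues had a Pearson correlation of 0.524 and a Spearman correlation of 0.458. Without the low-count filter the Pearson correlation was 0.268. Genes higher at D10 in both tissues numbered 403, against 113.1 for independent lists of these lengths, and genes lower in both 202, against 68.47. ICM and TE libraries of a stage came from the same litters, and part of the excess can come from that. The numbers for independent lists also take every gene as equally likely to be called, whatever its level. Trophectoderm in the ICM libraries, of which the share was not measured, would carry changes of the TE into the ICM. The agreement therefore does not by itself show a shared response. Another 34 genes were higher in the ICM and lower in the TE at D10, and 11 the other way round.

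Among the gene lists cholesterol synthesis had the smallest p for the difference of the changes, tested as an interaction. Of the 20 tested genes 15 had a more positive change in the ICM than in the TE and 0 a more negative one (19 and 0 adjusted over the list alone), with a median log2 difference of 2.83 (adjusted p = 5.7e-22). Sqle differed by 3.60 ± 0.52 (adjusted p = 6.5e-05). Lrp2, the endocytic receptor megalin (ENSMUSG00000027070, GRCm38 chromosome 2, 69424340 to 69586065, minus strand), differed by 7.33 ± 1.05 (adjusted p = 6.5e-05), with a change of 1.27 ± 0.58 in the ICM (adjusted p = 0.115) and of -6.06 ± 0.86 in the TE (adjusted p = 1.28e-05). Gsta4 differed by 2.41 ± 0.30 (adjusted p = 7.92e-06). The more positive change was in the TE for Slc1a5, a glutamine transporter (log2 -4.98 ± 0.80, adjusted p = 0.000286), Cdc25a, a cell cycle phosphatase (log2 -2.10 ± 0.36, adjusted p = 0.000784), and Baz2b, a chromatin reader (log2 -3.02 ± 0.54, adjusted p = 0.000991). Serf2, Rpl37, Rpl37rt and Rpl32 passed too, but Serf2, Rpl37rt and Rpl32 share 3′ sequence with other genes, Rpl37rt is a copy of Rpl37, and all 4 are uncertain. Of the 50 genes with the smallest p for the interaction, 32 share 3′ sequence or are pseudogenes.

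**Figure D4:**
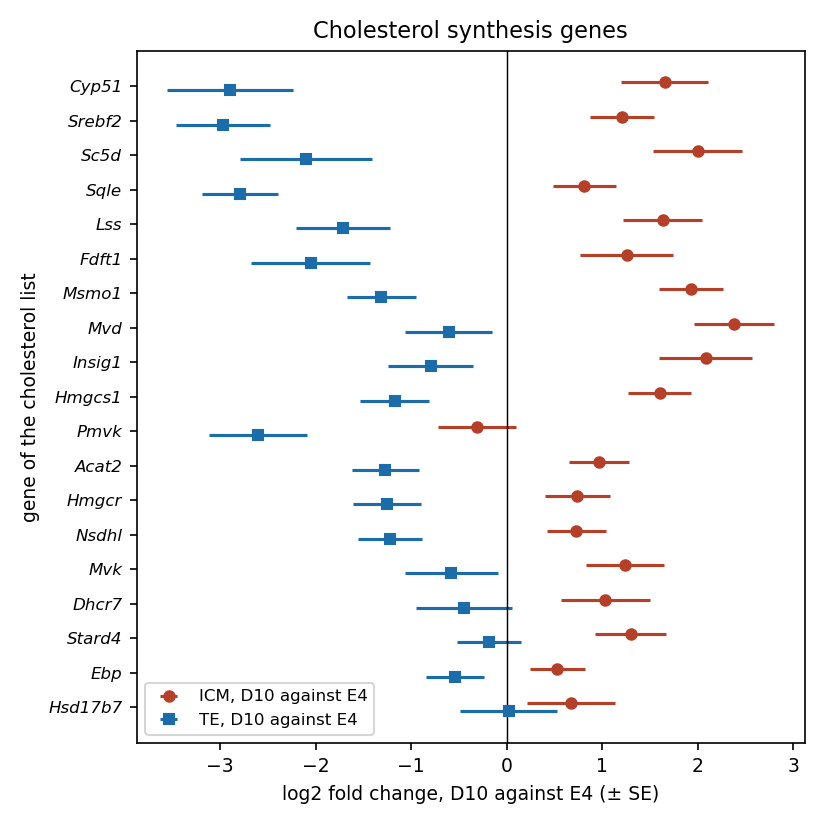
Log2 fold change from E4 to D10 of 19 of the 20 tested cholesterol synthesis genes on the horizontal axis, with 1 gene per line. Circles give the ICM, squares the TE and bars the SE, and 18 of the 19 ICM values lie above 0 and 18 of the 19 TE values below 0.

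Other lists passed for the difference of the changes with few single genes, given here as genes with a more positive and a more negative change in the ICM. Ribosome biogenesis had 0 and 2 of 46 (adjusted p = 0.000793), primitive endoderm 2 and 0 of 24 (adjusted p = 0.00376). Actin cytoskeleton had 2 and 0 of 36 (adjusted p = 0.004) and trophectoderm 4 and 0 of 29 (adjusted p = 0.0102). Lrp2 is counted in both the primitive endoderm and the trophectoderm list here. The S phase list had 0 and 4 of 47 (adjusted p = 0.00648) and did not pass without D10 ICM replicate 3 (adjusted p = 0.0533). The mitosis list had 1 and 0 of 52 (adjusted p = 0.0126), proteasome 0 and 0 of 33 (adjusted p = 0.0194) and translation factors 0 and 1 of 36 (adjusted p = 0.0258). Antioxidant genes had 3 and 0 of 29 (adjusted p = 0.0302) and immediate early genes 1 and 0 of 15 (adjusted p = 0.0322). Myc targets had 0 and 1 of 23 (adjusted p = 0.0355) and oocyte genes 1 and 0 of 3 (adjusted p = 0.0184). Each of these 7 failed with at least 5 different libraries left out 1 at a time.

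The interaction called 219 genes with a more positive and 127 with a more negative change in the ICM. Thinned libraries gave 122 and 55, and no filter 352 more positive genes. The fit without E4 litters with a zona gave 144 and 54, the fit without shared genes and pseudogenes 74 more negative genes, and the fit without D10 ICM replicate 2 gave 83.

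At the preset correlation 10 lists passed in no comparison, with a lowest adjusted p of 0.0666: adhesion and matrix, amino acid transport, FoxO targets, Lif and STAT3, genes of the mitochondrial genome, mTORC1 and insulin, Myc and its partners, ribosomal proteins, the tricarboxylic acid cycle and YAP. Of the 80 ribosomal protein genes tested, 67 share 3′ sequence with other genes. The formative pluripotency list had 2 tested genes and the blood and immune list 0, too few to be tested as sets.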

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

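The tests of parent and copy pairs, of Rpl37 with Rpl37rt and of low counts, and for the cholesterol list those of shared reads, trophectoderm and primitive endoderm, were chosen after the results were seen. The tests without the E4 litters with a zona were chosen after the data were seen, and the remaining tests before.

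Cholesterol synthesis genes moved in opposite directions in the ICM and the TE between E4 and D10, with a median log2 difference of the changes of 2.83 over 20 genes. In the set test with an estimated correlation the difference passed (adjusted p = 0.0463). The change within the ICM (0.406) and within the TE (0.26) did not. The mean level of the list, as log2 (CPM + 1), was 5.61 ± 0.138 in E4 ICM, 5.84 ± 0.407 in E4 TE, 6.58 ± 0.977 in D10 ICM (from 4.99 in replicate 3, below every E4 ICM library, to 7.64) and 4.43 ± 0.208 in D10 TE. Without the E4 litters with a zona the median was 2.89, which argues against zona status as the explanation. With all libraries at 1 total (sequencing depth) it was 2.81, but thinning leaves the expected ratio of CPM values as it was. Without the 1 member with shared 3′ sequence (reads shared with copies) it was 2.88, but 1 member of 20 can hardly move a median. The values for depth and shared reads therefore decide nothing. More trophectoderm in 1 of the ICM groups could not give the rise in the ICM, since the tissues differed at E4 by a median of -0.177, against a change of 1.25 in the ICM. More primitive endoderm in the D10 ICM cannot be told apart from regulation within cells. The primitive endoderm list rose by a median of 1.2, close to that of the cholesterol list. The lineage factors Sox17 (log2 0.84) and Gata4 (0.62) rose by less without passing, but their SE do not set them apart from that median. Gata6 fell (-1.04), but it was counted in the TE too, and its call was lost without the E4 litters with a zona. These lineage factors do not decide the question. The pool cannot be told apart either, as each group was 1 amplification pool. A change of sterol synthesis with diapause, different in the tissues, stays open as the biological explanation and was not tested on its own.

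Genes with shared 3′ sequence and pseudogenes, 736 of the 6943 tested, were called more often than the other genes across time, 34.2% against 22.4% in the ICM and 31% against 20.7% in the TE, and for the interaction, 13.3% against 4%. Between the tissues the shares were 32.9% against 31% at E4 and 23.6% against 25.7% at D10. Low counts do not account for it in the ICM or the interaction, where among genes above the median level the shared genes were called 1.57 and 2.9 times as often, and in the TE the ratio of 1.31 leaves it open. If reads had moved between a parent gene and its processed copy, the pair would change in opposite directions. Of the 46 pairs with a called copy 28.3% did so (95% interval 16% to 43.5%). Each pair was taken in the pairwise comparison with the smallest adjusted p, often one between the tissues, where there was no such excess. Copies stood at a median of 40.1% of the parent's level and as low as 1.16%, and some parents hardly changed. The share therefore cannot decide on such moves across time. For 1 pair such a move may hold: in the TE Rpl37 had a log2 change of -1.27 and Rpl37rt of 3.86, and their summed counts changed by 0.356 ± 0.235 (adjusted p = 0.298). In the ICM both rose (1.385 and 0.893) and the summed counts rose by 1.35 ± 0.239 (adjusted p = 0.00022). A move between these genes alone would not give that rise. Shifts among several copies of 1 family, or between pools, stay open, and no biological explanation was tested.

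The changes between E4 and D10 were set against the zona and the depth. With the E4 litters that had a zona left out, 99.7% of the 1642 called genes still tested in the ICM and 99.9% of 1508 in the TE kept their direction with at least 0.5 of the log2 change. With all libraries at 1 total the shares were 99.5% of 1093 and 99.4% of 994. These genes had been called in the same libraries, so high shares were likely beforehand. Thinning also leaves the expected ratio of CPM values as it was, so the shares cannot decide on depth. Without the zona litters 1105 genes were called in the ICM and 1135 in the TE, so zona status does not explain these changes as a whole. That fit, with fewer libraries, kept 988 of 1643 calls in the ICM and 978 of 1513 in the TE. The pool of each group and the difference in litters cannot be told apart from diapause.

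For the number of genes called in each comparison, of 100 splits of the same libraries only the real one, 1 of 100, gave as many. Every other split mixes libraries of the real groups, so their differences widen the spread within the new groups. Few calls follow from that alone, and these counts cannot exclude chance or an effect of the pool. In the ICM across time 1643 genes were called against at most 99 in other splits, and in the TE 1513 against 64. Between the tissues 2165 genes were called at E4 against 308, and 1771 at D10 against 501. Among the 15 other splits that part all 5 litters, as the real one does, the highest counts were 170 at E4 and 48 at D10. The larger counts were in splits that keep ICM and TE of some litters together, but most of those gave no calls. What raised the larger counts was not tested. For the interaction 346 genes were called against 1.

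The changes of the ICM and the TE differed by the interaction test in these genes: Serf2 (log2 difference 3.78), Gsta4 (2.41), Rpl37 (2.66), Lrp2 (7.33), Sqle (3.60), Rpl37rt (-2.96), Slc1a5 (-4.98), Rpl32 (-1.68), Cdc25a (-2.10) and Baz2b (-3.02). Of these Serf2, Rpl37rt and Rpl32 have shared 3′ sequence. Among lists the median log2 difference was -0.473 for ribosome biogenesis, 0.332 for primitive endoderm, 0.557 for actin cytoskeleton, -0.334 for S phase, 0.338 for trophectoderm, 0.373 for mitosis, 1.36 for the 3 oocyte genes, -0.253 for proteasome, -0.35 for translation factors, 0.259 for antioxidant, 0.94 for immediate early and -0.372 for Myc targets. Leaving out members with at most 3 counts in a group moved 3 of these medians, to 0.584 for primitive endoderm, 0.451 for trophectoderm and 2.65 for oocyte genes.

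In 7 of 108 groups of libraries checked, over 6 measures per library, 17 genes, the cholesterol mean and 3 lists of other cell types, 1 library lay apart from the rest by more than 0.71 of the group's range. Chance does this in about 1 of 20 groups. Sox2 had 5.75 CPM in E4 TE replicate 1 and 0 in the other 4 libraries. Gata6 had 26.8 CPM in E4 TE replicate 3 against 135 to 179, and without that library its change in the TE reversed, to a log2 of -0.07 from 0.25. Gata4 had 28.6 CPM in E4 TE replicate 5 against 0 to 2.43. Cdx2 had 61 CPM in D10 ICM replicate 2 against 27.9 to 33.6, and Plk1 192 CPM in D10 ICM replicate 4 against 64.3 to 92.9. Blood and immune markers summed to 92.1 CPM in E4 TE replicate 1 against 0 to 12.2, and to 71.6 CPM in D10 TE replicate 4 against 14 to 26.5.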

How the results depend on the processing

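Leaving out the E4 replicates with a zona, leaving out shared genes and pseudogenes, and the litter block for gene lists were chosen after the data were seen, and the other alternatives before. The cause of the differences was not tested unless it is given.

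Numbers of genes higher and lower moved by over 1.5 times under these settings. Thinning all libraries to 144276 counts, which leaves fewer counts and fewer genes tested, gave 509 and 360 in the ICM across time, 410 and 354 in the TE, 568 and 662 between the tissues at E4, 443 and 459 at D10, and 122 and 55 for the interaction. A minimum count of 30, with fewer genes tested, gave 531 higher genes in the TE, 660 higher at E4, and 596 and 574 at D10. No filter gave 1474 higher genes at D10 and 352 for the interaction. Without the E4 replicates with a zona, 379 genes were lower in the ICM, and the interaction called 144 and 54. Without shared genes and pseudogenes it called 74 lower genes.

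Leaving out 1 library at a time gave 839 to 1049 higher and 487 to 685 lower genes in the ICM across time and 674 to 855 and 604 to 781 in the TE. It gave 860 to 1096 and 1000 to 1180 at E4, 786 to 1001 and 710 to 899 at D10, and 194 to 256 and 83 to 128 for the interaction, where the lowest, 83, was without D10 ICM replicate 2. The number of list tests that passed, 71, ran from 62 to 73.

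The correlation of the changes of the tissues, 0.524, was 0.268 with no filter, 0.569 with the stricter minimum, 0.544 in thinned libraries, 0.507 with voom, 0.567 with only the groups compared, 0.470 without the E4 zona replicates, 0.560 without shared genes, and 0.48 to 0.529 with 1 library left out. With an estimated correlation 10 list tests passed.

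Of the 1162 genes called at D10 and still tested in thinned libraries, 1 had the opposite direction there. The other results that reversed were of genes and lists that did not pass. In the ICM across time Sox2 was at log2 -0.006536 with voom and -0.002229 with a block of replicate numbers, which pair nothing across time. With 1 library left out it ran from -0.246 to 0.324, below 0 without E4 ICM replicate 4 or D10 ICM replicate 3 or 5, and Krt8 from -0.5246 to 0.08961, above 0 without D10 ICM replicate 1. In the TE Gata4 ran from -0.4269 without D10 TE replicate 1 to 2.88 without E4 TE replicate 5, and Gata6 from -0.06514 without E4 TE replicate 3 to 0.3668. Krt8 was at -0.2006 in thinned libraries and ran from -0.1075 to 0.2571, below 0 without E4 TE replicate 1 or 3 or D10 TE replicate 1 or 4. The Lif and STAT3 list at D10 reversed under the stricter minimum and in thinned libraries (adjusted p = 0.881 and 0.943). The ribosomal protein list for the interaction had an adjusted p of 0.045 without D10 TE replicate 5 to 0.999, and reversed without D10 TE replicate 4.

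Of 424 calls of named genes, 394 were kept with any 1 library left out and 30 were lost at least once. The calls lost were 3 with DESeq2 size factors, 4 with DESeq2's Wald test, 3 with voom, 18 with no filter, 20 in thinned libraries, 4 with only the groups compared, 29 without the zona replicates and 4 without shared genes, with 0 lost under the stricter minimum among those still tested. Of 71 list calls, 50 were kept with any 1 library left out. List calls lost were 1 with DESeq2 size factors, 6 with no filter, 10 under the stricter minimum and 12 in thinned libraries. Another 9 were lost without the zona replicates and 11 without shared genes. Gained were 13 with no filter, 1 under the stricter minimum, 2 in thinned libraries, 5 without the zona replicates and 4 without shared genes. Not all of these losses are named beside the list concerned.

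With litter as a replicate block, 2356 genes were called between the tissues at E4, 1952 at D10 and 496 for the interaction, and 0 of 222 named genes changed their call. Of list calls, autophagy and lysosome at D10 was lost (adjusted p = 0.0702), and glycolysis at D10 (0.0204) and quiescence (0.033) and mural and giant cell markers (0.0212) for the interaction were gained. It changed no other call of a named gene or list. Leaving out libraries under 0.25 of the median total removed none, so that setting gave no values.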

Other observations

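The comparison of E4 libraries with and without a zona, the pairs of E4 litters left out, and the counts and examples of shared genes were chosen after the data were seen.

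Pseudogenes and genes with shared 3′ sequence led the difference of the changes between ICM and TE. They made up 32 of the 50 genes with the smallest p for the interaction (64%), against 10.6% of all tested genes. Some stood far above in 1 group, with a narrow spread between its 5 libraries. Gm13340 (ENSMUSG00000083563), an unprocessed pseudogene, had 6750 ± 1470 CPM in D10 ICM and 85.5 ± 11.2 in E4 ICM, 170 ± 43.5 in E4 TE and 104 ± 20.9 in D10 TE. Gm29216 (ENSMUSG00000101249), also an unprocessed pseudogene, had 2520 ± 465 CPM in D10 TE, 424 ± 95.1 in E4 ICM, 130 ± 28.6 in E4 TE and 370 ± 62.8 in D10 ICM. Gm14336 (ENSMUSG00000082543), a processed pseudogene, had 594 ± 108 CPM in E4 TE and 3.18 ± 3.34, 3.21 ± 3.46 and 3.62 ± 2.04 in E4 ICM, D10 ICM and D10 TE. These 3 genes lie outside the rule for naming genes. At least 4-fold above each of the other groups in 1 group were 3.67% of shared genes (27) and 1.72% of other genes (107). The shared ones numbered 0 in E4 ICM, 11 in E4 TE, 9 in D10 ICM and 7 in D10 TE, and the others 20, 12, 42 and 33. As each group was 1 amplification pool, pool and group cannot be told apart here. Whether the 4 pools were aligned and counted with the same settings for reads that map to several places is not stated either, so these values may not be comparable between groups.

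Within E4, the 2 libraries per tissue from litters with a zona were compared with the 3 without by edgeR's quasi-likelihood test, the only tool run on this. In the ICM 0 genes passed, with 347 at an unadjusted p under 0.05. In the TE 1 gene passed, Ccng2, lower with a zona (log2 -3.51, adjusted p = 0.00569), with 480 at an unadjusted p under 0.05. Leaving out both zona litters gave 1105 called genes across time in the ICM and 1135 in the TE, within the 950 to 1350 and 940 to 1204 of the other 9 pairs of E4 litters left out. Between the tissues at E4 it gave 1685, against 941 to 1628, at D10 1936, against 1701 to 1932, and for the interaction 198, against 129 to 180.

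Lists meant as markers of other cell types were summed per library. Of the uterine list, Foxa2 is also in the primitive endoderm list and Lif in the Lif and STAT3 list. These sums, and the set tests of these lists, cannot tell other cells from transcripts of the embryo itself. Uterine markers summed to 324 ± 142 CPM in E4 ICM, 326 ± 68.8 in E4 TE, 588 ± 113 in D10 ICM and 785 ± 62.2 in D10 TE, with Msx1 the most abundant in E4 ICM (153 CPM) and Wfdc2 in the other groups (156, 193 and 445 CPM). Oocyte and cumulus markers summed to 762 ± 230, 614 ± 263, 219 ± 72.7 and 111 ± 58.5 CPM in the same order, with Khdc3, which shares 3′ sequence with other genes and is uncertain, at 523, 458 and 90.9 CPM in the first 3 groups, and Zp2 at 73 CPM as the most abundant in D10 TE. Blood and immune markers summed to 27 ± 12.1, 22.5 ± 39.2, 81.2 ± 69.4 and 29.4 ± 24.1 CPM.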
